A study of Mus musculus with 24 samples.

How the data were processed

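Gene expression was measured on Illumina bead arrays in livers of male mice, 20 weeks old, on a C57Bl6/J background. Per the labels, total RNA was extracted with Trizol, cleaned on a column with DNase treatment, and labelled as biotinylated cRNA with an Ambion kit. The 24 arrays held 12 groups, 1 for each of 2 genotypes and 6 times of day, with 2 arrays per group that the labels call technical replicates. Whether an RNA sample came from 1 animal or from a pool is not given in the sources used here.

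Scanner output was exported with GenomeStudio, per the submitters' processing notes, and its version is not given in the sources used here. The deposited signal is an intensity on a linear scale, the mean over the beads of a probe, with no normalization between arrays, per the file headers. The deposited detection p-value compares a probe with the negative controls of its array, per the file headers, which also give bead numbers and the standard error over beads. A further deposited table holds the authors' processed intensity values. Its medians were 278.76 to 278.97 on every array, its values were on a linear scale, and its Spearman correlation with the unprocessed signals was 1 on each array. No centring of genes was seen, and the normalization method stays unknown. No genome build is given in the sources used here, and no coordinates were used.

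Probes were named through the platform annotation. Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none listed there. Symbols were checked through Entrez identifiers against a RefSeq gene table, which updated 0 of them. Array intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected by the normexp method with control parameters inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. Probes were kept if detected (detection p under 0.01) on both arrays of at least 2 of the 12 groups, which left 10243, of which 586 had no gene listed. For each symbol the kept probe with the highest mean was used, giving 7272 genes. Where several probes of a named gene were kept, they had the same direction except for Acta2, although sizes differed for some. A group with no array above the detection limit has only a bound, and the fold is then given as at least the mean of the other group over a floor, the higher of the lowest detected signal on each array and the signal of the probe itself.

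The number of independent values, 1 for each genotype and time, limits the precision. Arrays had 38.1 to 40.6 beads per probe on average and 8940 to 10339 detected probes. The 2 arrays of a group differed with a variance of 1.28 to 1.66 times the bead error, against at least 2.60 to 4.17 times for other times of the same genotype, so they were averaged and counted as 1 value. The mean of the array medians was 309.8 on slide 1, 283.2 on slide 2 and 252.4 on slide 3 before normalization.

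A harmonic model with a 24 h period and a mean for each genotype was fitted to the 12 averages with limma (6 residual and 3.32 prior degrees of freedom). Tests were of the DKO minus WT daily mean, of rhythm in each genotype, and of the difference in rhythm, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. SE values are those of the moderated fit. The 27 gene lists were tested with limma's camera at a preset correlation of 0.01 where at least 3 genes were measured, which held for 21, and again with an estimated correlation. At each time, with 1 RNA sample per genotype, a gene was counted where the lowest array of 1 genotype lay above the highest of the other by at least 1 on the log2 scale, with no test.

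The groups, tests, gene lists and the alternatives were fixed before the data were examined, except where stated. Named genes were all measured clock-list genes, the 8 largest rises and 8 largest falls in daily mean among genes that passed with the same direction at 6 of 6 times, the 8 largest amplitudes among genes that passed for each rhythm test, up to 4 genes that passed in each other list (or the 1 with the largest change where none did), and the 2 furthest up and 2 furthest down at each time. Predicted transcripts were passed over. Further members of the fixed lists that passed, the genes 2-fold apart at all 6 times, some of the genes that went opposite ways between times, and the immune genes of the DKO ZT0 sample were named after their values were seen.

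Alternatives were normexp with an offset of 50, no background correction, median scaling in place of quantile normalization, the authors' values, no filter on dim probes, probes detected on all 24 arrays, all kept probes as separate tests, arrays as separate samples with and without a block, slide as a fixed or random block, an intensity trend with robust variances, time as a factor, each genotype fitted alone, a 1.5-fold minimum, and leaving out each time and each array. None of the 54 named genes called in daily mean turned its direction with median scaling. The fitting steps were tested on simulated data with 200 changed genes among 7272 in 5 runs. For the daily mean, 89.1% of changes of 1 and 98.8% of changes of 2 (log2) were recovered. For WT rhythm 84.6% and 99.2% were recovered, for DKO rhythm 85.4% and 98.9%, and for the difference in rhythm 58.3% and 95.5%. False calls made up 3.8 to 5.91% of calls. The simulated values had independent noise and no slide effect, so these rates do not carry over to calls in the real data, where slide and genotype go together.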

Results

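Gene expression was measured in livers of wild-type (WT) mice and of mice whose liver lacks both Rev-erb receptors, alpha and beta (double knockout, DKO). These nuclear receptors, encoded by Nr1d1 and Nr1d2, repress transcription and are part of the circadian clock. The knockout was made with an albumin-driven Cre recombinase. RNA was taken every 4 h from ZT0 to ZT20, where ZT counts hours from lights on, and was hybridised to Illumina bead arrays. Each genotype and time had 2 arrays, which the labels call technical replicates, so the 24 arrays were averaged to 12 values, 6 per genotype. The number of animals behind each RNA sample is not given in the sources used here. The p-values therefore measure only the spread between these samples, which may be technical, with the times of day standing in for replicates. The median raw signal per array was 245 to 341 units and 34.8 to 40.2% of 25697 probes were detected. The 2 arrays of a group correlated at 0.990 to 0.995, with an SD between them of 0.161 to 0.223 on the log2 scale. The number of independent values, 6 per genotype, limits the precision. The arrays lay on 3 slides. Slide 1 held DKO ZT0 to ZT12, slide 2 held DKO ZT16 and ZT20 with WT ZT0 and ZT4, and slide 3 held WT ZT8 to ZT20. No time of day had both genotypes on 1 slide, so slide and genotype cannot be told apart at any single time. Values with slide in the model and within slide 2 are given for the gene lists and for the genes named as changed in daily mean, except Moxd1. Within slide 2, DKO ZT16 and ZT20 are compared with WT ZT0 and ZT4. Those values therefore also hold a difference between times of day, which can be large for genes that cycle.

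The first question was what became of the clock genes. Transcripts of both targeted genes were still detected in DKO liver. Nr1d1 was at 7.19, 10.50, 9.41, 9.08, 7.19 and 6.41 (normalized log2 intensity, ZT0 to ZT20) in WT and at 9.59, 11.03, 10.58, 9.77, 9.59 and 8.81 in DKO. Nr1d2 was at 7.70, 9.44, 10.45, 10.91, 9.62 and 8.35 in WT and at 9.57, 9.89, 10.06, 10.02, 10.13 and 9.90 in DKO. The daily mean of Nr1d1 rose 3.02-fold (1.60 ± 0.29 log2, SE, n = 6 times per genotype) and that of Nr1d2 rose 1.43-fold (0.52 ± 0.12), with limma adjusted p of 0.0135 and 0.0265, higher at 6 and 4 of 6 times. Fitted with slide as a fixed block the differences were 1.24 and 0.76, and within slide 2, between different times, they were 0.35 and 1.45. Where the probes lie relative to the deleted part of each gene is not given in the sources used here, so these signals check nothing about the deletion. The WT profile of Nr1d2 had a fitted amplitude of 1.55 (log2, limma adjusted p = 0.00345) with a peak at ZT 10.6, against 0.22 in DKO (limma adjusted p = 0.800).

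Of 5 measured genes of the positive limb of the clock, which drive clock transcription or are targets of the Rev-erb receptors, 3 rose and 2 did not pass. Arntl, which encodes the clock activator BMAL1, rose 2.84-fold in daily mean (1.51 ± 0.36 log2, SE, n = 6 times per genotype, limma adjusted p = 0.0312). It was not detected in WT at ZT8 and ZT12 and reached 9.65 at ZT4, whereas DKO stayed between 9.45 and 9.87. Nfil3, a repressor of D-box genes, rose 2.14-fold (1.09 ± 0.29, limma adjusted p = 0.0470), but its direction turned with slide as a fixed block (-0.06), and it differed by 0.33 within slide 2. The same values were 0.66 and 0.21 for Arntl. Npas2, a partner of BMAL1, rose too (limma adjusted p = 0.00634), but it was detected on 0 of 12 WT and 5 of 12 DKO arrays, so no fold is given, with differences of 1.12 under the fixed block and 0.84 within slide 2. Clock (0.33 ± 0.14) and Rora (0.01 ± 0.14) did not pass. The list lay 0.78 log2 above the other genes (camera adjusted p = 0.0219, limma), and adjusted p = 0.658 with an estimated correlation. The shift was 0.32 with slide as a fixed block and 0.29 within slide 2. Without ZT20 the list no longer passed, with a shift of 0.69 and camera adjusted p = 0.0670 (limma), and it did not pass among probes detected on all 24 arrays, with 0.47 and 0.249.

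In the negative limb, 0 of 6 measured genes passed limma's test for the daily mean, and 0 of the 6 had an unadjusted p under 0.05. The differences were 0.01 ± 0.33 for Per1, -0.23 ± 0.28 for Per2, -0.15 ± 0.20 for Per3, -0.25 ± 0.18 for Cry2, 0.32 ± 0.19 for Ciart and 0.10 ± 0.19 for Bhlhe40 (log2, SE, n = 6 times per genotype). Of 5 measured clock output genes, 1 rose. Dbp, a D-box activator driven by the clock, rose 2.63-fold (1.39 ± 0.26, limma adjusted p = 0.0135) and was higher at 4 of 6 times, with the lowest WT level, 8.23 at ZT0, against 11.66 in DKO. Its difference was 2.65 with slide as a fixed block and 2.43 within slide 2, between different times. Tef (-0.03 ± 0.22), Usp2 (-0.72 ± 0.35), Nampt (-0.35 ± 0.14) and Alas1 (0.13 ± 0.18) did not pass. The shifts of the negative limb (-0.04) and clock output lists (0.08) did not pass either (camera adjusted p of 0.890 and 0.981, limma), and for clock output the median (-0.03) and the test pointed down. With slide as a fixed block they were 1.10 and 1.11, and within slide 2, between different times, they were 1.05 and 1.47. Of the 18 genes of the clock lists, 6 changed in daily mean adjusted over the list alone and 6 over all genes. Among those 6, the limma call ended without ZT16 for all, namely Nr1d1 (adjusted p = 0.0727), Nr1d2 (0.128), Arntl (0.0659), Npas2 (0.0564), Nfil3 (0.118) and Dbp (0.0757), and without each of ZT8, ZT12 and ZT20 for 5 of the 6. The exceptions were Npas2 without ZT8 (0.0386) and ZT12 (0.03), and Dbp without ZT20 (0.0348). Without ZT0 it ended for Arntl (0.0942) and Nfil3 (0.162).

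**Figure D1:**
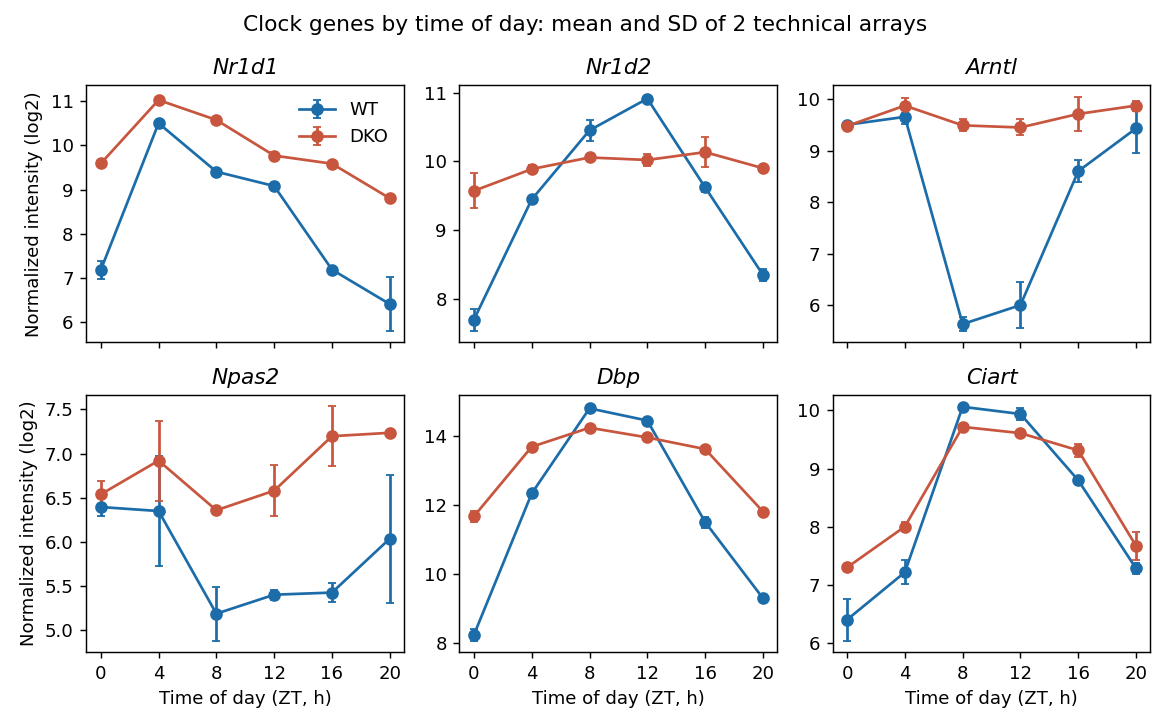
Normalized log2 intensity (vertical axis) of 6 clock genes against time of day (horizontal axis, ZT in h) in WT and DKO liver; points are means and bars the SD of the 2 technical arrays. WT Arntl lies near 6 at ZT8 and ZT12, where it was not detected, while DKO Arntl lies between 9.45 and 9.87; Dbp reaches 8.23 in WT and 11.66 in DKO at ZT0.

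The second question was which transcripts cycled over 24 h. In WT, 13 genes had a daily rhythm (limma, harmonic model). The 8 with the largest amplitude peaked in 2 parts of the day. Dbp (amplitude 3.39 ± 0.26 log2, SE, n = 6 times, limma adjusted p = 0.00345), Nr1d2 and the clock repressor Ciart (1.94 ± 0.19, limma adjusted p = 0.0104) peaked between ZT 9.82 and ZT 11.3. The fatty acid elongase gene Elovl3 (1.93 ± 0.21, limma adjusted p = 0.0212), Tubb2b, the glycogen-targeting subunit gene Ppp1r3c (1.62 ± 0.20, limma adjusted p = 0.0317), Clpx and Dtx4 peaked between ZT 22.6 and ZT 23.9. All 13 had a lower fitted amplitude in DKO, with a median of 0.22 against 1.29 in WT. These genes were picked by their WT rhythm, which favours a high WT amplitude.

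In DKO, 4 genes had a daily rhythm, and 0 had one in both genotypes. Lifr, which encodes a cytokine receptor subunit, had an amplitude of 1.27 ± 0.12 with a peak at ZT 8.67 (limma adjusted p = 0.0210), and Mcm10 had 0.77 ± 0.08 with a peak at ZT 9.61 (limma adjusted p = 0.0395). Arhgap25 (0.98 ± 0.10) and Rgs5, a pericyte gene (0.86 ± 0.08), peaked at ZT 22.6 and ZT 23.2. Arhgap25 was detected on 4 and Rgs5 on 5 of 12 DKO arrays.

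The test of the difference in rhythm called 0 genes with limma, with 450 genes at an unadjusted p under 0.05, where 364 would pass by chance. The same counts were 1001 for WT rhythm and 538 for DKO rhythm. A gene rhythmic in 1 genotype was therefore not shown to differ from the other genotype over all genes. Adjusted over the list alone, 16 of the 18 genes of the clock lists were rhythmic in WT, 2 in DKO (Ciart and Dbp), and 6 differed in rhythm between genotypes, against 3, 0 and 0 over all genes. The 6 were Nr1d2, Arntl, Cry2, Bhlhe40, Dbp and Nampt. Npas2, among the 16 rhythmic in WT, was detected on 0 of 12 WT arrays, so that call rests on undetected signals. Fitted with slide as a fixed block, the counts adjusted over the list alone were 8 in WT, 2 in DKO and 1 for the difference, which was Nr1d2, itself a targeted gene (limma). The amplitude was then 1.57 in WT and 0.30 in DKO for Nr1d2, 1.69 and 0.27 for Arntl, 3.19 and 1.76 for Dbp, 0.307 and 0.452 for Cry2, 0.08 and 0.38 for Bhlhe40, and 0.325 and 0.322 for Nampt. Slide as a random block gave 14, 2 and 2, and the 2 were Nr1d2 and Dbp (limma adjusted p of 0.000928 and 0.0125). The 16 clock-list genes other than the targeted genes had a mean amplitude of 1.22 in WT and 0.52 in DKO, a difference of -0.70 ± 0.56 (SD over genes), lower in DKO in 15 of 16. The fit with slide as a fixed block gave means of 0.83 and 0.61, a difference of -0.22 ± 0.56, where 10 of 16 were lower in DKO, the exceptions being Per1, Per2, Cry2, Bhlhe40, Usp2 and Alas1. The random block gave a difference of -0.64 ± 0.55. In the fit without slide, swapping the genotypes within times gave an exact two-sided p of 0.03125, the smallest the 6 times allow, and 0.09375 after adjustment over the 3 gene sets tested. This test was added after the data were seen. Without any 1 time the exact p was 0.0625, again the smallest the design allows.

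The rhythm counts depended on single times and on the normalization. Without ZT0, ZT8, ZT12, ZT16 or ZT20, limma called 6, 1, 2, 4 and 4 genes rhythmic in WT, and without ZT0, ZT4, ZT8, ZT12, ZT16 or ZT20 it called 0, 2, 0, 0, 0 and 0 in DKO (349 to 668 at an unadjusted p under 0.05 where it called 0), and 1 gene differed in rhythm without ZT0. The WT count was 37 to 123 under the other background and scaling choices, 8 with slide as a random block and 0 with slide as a fixed block (limma, 708 at an unadjusted p under 0.05). The DKO count was 1 with the fixed block, and 0 of the 4 genes named above were among its calls. With the fixed block the amplitude was 1.49 in WT and 1.41 in DKO for Ciart, 1.55 and 0.22 for Elovl3, 1.555 and 0.21 for Tubb2b, 1.44 and 0.66 for Ppp1r3c, 1.115 and 0.15 for Clpx, and 1.155 and 0.04 for Dtx4. For the genes rhythmic in DKO it was 0.38 in WT and 1.48 in DKO for Lifr, 0.40 and 0.75 for Mcm10, 0.17 and 1.01 for Arhgap25, and 0.23 and 0.85 for Rgs5. Slide 2 held 2 times of each genotype, which is too few to fit a rhythm.

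The third comparison was of the daily mean of the genotypes. Large rises in DKO were seen for Wfdc12 (8.44-fold, 3.08 ± 0.31 log2, SE, n = 6 times per genotype), for Lpl, which encodes lipoprotein lipase (7.65-fold, 2.94 ± 0.34), and for Cyp17a1, a steroid hydroxylase gene (7.44-fold, 2.89 ± 0.54). Ntrk2, a neurotrophin receptor gene, rose 6.09-fold, the cytochrome P450 gene Cyp2d12 5.80-fold, Gpnmb, a macrophage and lysosome glycoprotein gene, 5.14-fold, the trefoil factor gene Tff2 5.08-fold and the lysyl oxidase gene Loxl4 4.73-fold. Large falls were seen for the acyl-CoA thioesterase genes Acot3 (9.17-fold, -3.20 ± 0.45) and Acot1 (8.20-fold, -3.04 ± 0.28), for Fitm1, a lipid droplet gene (8.38-fold, -3.07 ± 0.29), for Clstn3 (7.39-fold, -2.89 ± 0.23) and for the kinase gene Aatk (5.93-fold, -2.57 ± 0.16). Serpinb1a, Tpm2 and Col27a1 were not detected on any of the 12 DKO arrays and were at least 3.27-fold, 2.93-fold and 1.80-fold lower there. These 16 genes had limma adjusted p between 0.000392 and 0.0355 and the same direction at 6 of 6 times.

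Several of the genes that rose were near the detection limit in WT. Wfdc12 was detected on 2, Ntrk2 on 6, Gpnmb on 4, Tff2 on 3 and Loxl4 on 1 of 12 WT arrays, and Fitm1 on 3 of 12 DKO arrays, so their folds rest partly on undetected signals. Another Ntrk2 probe differed by 0.96 log2, against 2.61 for the one used. Acot1 and Acot3, and Cyp2d12, belong to families of similar sequence whose probes can share signal, and their separate values are uncertain. Of the 16, the limma call held with each time left out in turn for all but Cyp17a1, Ntrk2 and Gpnmb. Cyp17a1 had adjusted p of 0.0888, 0.0827 and 0.0837 without ZT8, ZT12 and ZT16. Ntrk2 had 0.160, 0.0806, 0.0844 and 0.124 without ZT8, ZT12, ZT16 and ZT20. Gpnmb had 0.108, 0.149, 0.159 and 0.113 without ZT4, ZT8, ZT16 and ZT20. With slide as a fixed block the differences were 1.71 for Wfdc12, 0.98 for Lpl, 4.69 for Cyp17a1, 4.81 for Ntrk2, 2.62 for Cyp2d12, 6.07 for Gpnmb, 1.36 for Tff2 and 1.91 for Loxl4. For the genes that fell they were 0.17 for Acot3, -1.52 for Fitm1, -1.75 for Acot1, -1.52 for Clstn3, -0.90 for Serpinb1a, -0.49 for Tpm2, -2.80 for Aatk and -1.74 for Col27a1. Within slide 2, between different times, Wfdc12 differed by 2.13, Lpl by 1.61, Cyp17a1 by 3.78, Ntrk2 by 2.96, Cyp2d12 by 1.77, Gpnmb by 4.43, Tff2 by 1.92, Loxl4 by 1.53, Acot3 by -0.64, Fitm1 by -2.37, Acot1 by -1.73, Clstn3 by -1.71, Serpinb1a by -2.76, Tpm2 by -1.81, Aatk by -1.99 and Col27a1 by -1.34.

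Over all 7272 genes tested, 677 differed in daily mean, 314 up and 363 down in DKO (limma, adjusted p under 0.05). At least 1.5-fold changes made up 372 of these, 175 up and 197 down, and 244 up and 304 down had the same direction at 6 of 6 times. With the arrays scaled to a common median instead of quantile normalized, 2182 genes passed, 186 up and 1996 down, so that 8.52% were up against 46.4%. That scaling moved the median difference of all genes from 0.02 to -0.20. Each of the 677 genes kept its sign, which was taken against 0 and not against that median. The spread of the raw signals, which median scaling leaves in place, went with slide 3. The 95th percentile over the lower quartile was 24.85 to 29.82 on the WT arrays of slide 3. It was 19.54 to 20.72 on the WT arrays of slide 2 and 18.25 to 21.47 on the DKO arrays. The count of genes in daily mean was 123 with slide as a random block and 0 with slide as a fixed block (limma, 793 at an unadjusted p under 0.05). With the fixed block the SE was a median of 2.83 times larger and 531 of the 677 (78.4%) kept their sign, against 52.2% of the other genes. Within slide 2, 609 of the 677 (90%) had the same sign, against 62.2% of the other genes. Both comparisons, with the fixed block and within slide 2, reuse samples that picked the 677 genes. Genes picked for a large difference keep their sign more readily, so neither share is independent support for the calls. Without ZT0, ZT8, ZT12, ZT16 or ZT20 the count was 366, 142, 149, 170 and 197. It was 541 without ZT4, 619 without the WT ZT4 sample alone and 499 without the DKO ZT0 sample alone.

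Of 14 measured genes of fatty acid oxidation and ketogenesis, 7 fell and 7 did not pass, and 11 fell adjusted over the list alone. Pdk4 (0.12) and Fgf21 (0.19) were among those that did not pass. Beside Acot1, the genes that fell were the fatty acid hydroxylase gene Cyp4a14 (3.91-fold, -1.97 ± 0.32 log2, SE, n = 6 times per genotype), Angptl4, an inhibitor of lipoprotein lipase (1.83-fold, -0.87 ± 0.21), Ppara, the nuclear receptor of the fasting response (1.75-fold, -0.81 ± 0.13), and the carnitine carrier and beta-oxidation genes Slc25a20, Acadl and Hadhb (-0.72, -0.52 and -0.43). The list shift was -0.71 (camera adjusted p = 3.8e-07, limma), and adjusted p = 0.272 with an estimated correlation. The shift was -0.49 with slide as a fixed block (camera adjusted p = 0.0508, limma) and -0.37 within slide 2, where the direction of Cyp4a14 turned (0.24, and -0.39 with the fixed block). The differences with the fixed block and within slide 2 were -0.64 and -0.69 for Angptl4, -0.35 and -0.29 for Ppara, -0.89 and -0.68 for Slc25a20, -0.30 and -0.31 for Acadl, and -0.28 and -0.27 for Hadhb. Cyp4a14 belongs to a family of similar genes and its probe can share signal. The single limma calls ended with some times left out, at adjusted p of up to 0.0574 for Cyp4a14 (without ZT20), 0.140 for Angptl4 (without ZT20) and 0.0666 for Ppara (without ZT16). Over the 6 times left out in turn, Cyp4a14 and Ppara kept the call for 3 and Angptl4 for 1.

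Of 14 measured lipid droplet and lipid uptake genes, 7 fell, 1 rose and 6 did not pass, with 8 and 1 adjusted over the list alone. Lpl was the gene that rose. Fitm1 fell (8.38-fold), and so did Cidea and Cidec, lipid droplet fusion genes, and Mogat1, which were not detected on any DKO array and were at least 1.45-fold, 1.07-fold and 1.18-fold lower there. Cidea was detected on 6 and Cidec on 5 of 12 WT arrays, so their falls rest partly on undetected signals. Cidea reached 10.73 and Cidec 9.47 in WT at ZT20, whereas at ZT8 the genotypes differed by 0.14 and 0.03. The lipolysis inhibitor G0s2 (2.28-fold, -1.19 ± 0.24 log2, SE, n = 6 times per genotype), Fitm2 (-0.64 ± 0.11) and the droplet coat gene Plin2 (-0.62 ± 0.16) fell as well. The list shift was -0.58 (camera adjusted p = 0.00671, limma), and adjusted p = 0.295 with an estimated correlation. The shift was -0.00 with slide as a fixed block and -0.18 within slide 2, and it did not pass with median scaling (camera adjusted p = 0.125, limma). Among probes detected on all 24 arrays, a filter that removes genes absent in DKO such as Cidea, it was 0.03 (camera adjusted p = 0.289, limma). The differences with the fixed block and within slide 2 were -0.87 and -1.65 for Cidea, -0.40 and -0.55 for Cidec, -0.04 and -0.55 for Mogat1, -0.94 and -0.66 for G0s2, -1.18 and -0.41 for Fitm2, and -0.48 and -0.49 for Plin2. The limma call of Cidea held only without ZT0, with adjusted p of 0.0658 to 0.134 without each of the other times. That of Cidec ended without ZT8 (0.0771) and without ZT12 (0.0814).

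In fatty acid and triglyceride synthesis, 1 of 19 measured genes rose, 1 fell and 17 did not pass, with the same counts adjusted over the list alone. The phosphatidate phosphatase gene Lpin1 rose 1.56-fold (0.64 ± 0.17 log2, SE, n = 6 times per genotype) and the desaturase gene Fads2 fell 1.28-fold (-0.36 ± 0.08). In cholesterol synthesis, 2 of 16 fell, over all genes and adjusted over the list alone, namely Pmvk (1.75-fold, -0.81 ± 0.18) and Idi1 (1.54-fold, -0.62 ± 0.16). In bile acid synthesis and transport, 1 of 15 fell by both counts, the bile acid uptake carrier gene Slc10a1 (1.55-fold, -0.64 ± 0.11). In glucose metabolism, 1 of 13 rose and 2 fell by both counts. The insulin receptor substrate gene Irs2 rose 2.49-fold (1.32 ± 0.34), and the glucose carrier gene Slc2a2 (1.68-fold, -0.75 ± 0.17) and the gluconeogenesis gene Pck1 (1.48-fold, -0.56 ± 0.12) fell. In xenobiotic metabolism, 3 of 15 rose and 4 fell by both counts. Cyp2c55 rose 3.77-fold (1.91 ± 0.30), Gstm3, which was detected on 4 of 12 WT arrays, 2.50-fold and Gstm2 2.43-fold, while Gsta2 fell 3.56-fold (-1.83 ± 0.49) and Aldh1a1 and the xenobiotic receptor genes Nr1i3 and Nr1i2 fell by 0.64, 0.63 and 0.47 on the log2 scale. The fold of Gstm3 rests partly on undetected signals, and glutathione transferase genes are similar in sequence, so their separate values are uncertain. The named genes of these lists had limma adjusted p between 0.00188 and 0.0499.

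None of these 5 list shifts passed (camera adjusted p of 0.257, 0.255, 0.255, 0.389 and 0.655, limma), and for glucose metabolism the median (-0.15) and the test pointed down while the mean was 0.01. With slide as a fixed block the shift was 0.82 in place of -0.13 for fatty acid and triglyceride synthesis, -0.58 in place of -0.15 for cholesterol synthesis, 0.16 in place of -0.13 for bile acid genes, 0.27 in place of 0.00 for glucose metabolism and 0.95 in place of -0.02 for xenobiotic metabolism. Within slide 2 the 5 shifts were 0.51, -0.47, 0.03, 0.34 and 0.46. Without ZT12 the 2 synthesis lists passed, with shifts of -0.25 and -0.30 (camera adjusted p of 0.0136 and 0.00252, limma). Of the 12 genes of these lists that the naming rule chose, Gstm2 alone was called by limma with each time left out in turn, and Lpin1, Fads2 and Idi1 lost the call whichever time was left out (adjusted p of 0.0506 to 0.169). Without ZT8 the call also ended for Pmvk (0.149), Slc10a1 (0.0746), Irs2 (0.116), Slc2a2 (0.147), Pck1 (0.0545), Cyp2c55 (0.0641), Gsta2 (0.175) and Gstm3 (0.114). Other Slc2a2 probes differed by -0.59 and -0.38, against -0.75 for the one used. The direction turned both with slide as a fixed block and within slide 2 for Slc2a2 (0.33 and 0.05), Gsta2 (1.66 and 0.09) and Nr1i2 (0.07 and 0.17), with the fixed block for Aldh1a1 (0.23, and -0.10 within slide 2), and within slide 2 for Fads2 (0.13, and -0.30 with the fixed block) and Pck1 (0.32 and -0.19). In the order of fixed block and slide 2, the other genes kept their direction, with 0.92 and 1.40 for Lpin1, -0.93 and -0.72 for Pmvk, -1.01 and -0.70 for Idi1, -0.45 and -0.70 for Slc10a1, 1.09 and 1.32 for Irs2, 2.94 and 1.81 for Cyp2c55, 2.47 and 1.62 for Gstm3, 1.57 and 1.33 for Gstm2, and -0.45 and -0.25 for Nr1i3.

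Of 4 measured cell cycle and growth arrest genes, 3 rose and 1 did not pass, with 3 up and 1 down adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a rose 4.54-fold (2.18 ± 0.33 log2, SE, n = 6 times per genotype), the growth arrest gene Gadd45g 2.55-fold (1.35 ± 0.20) and the cyclin D1 gene Ccnd1, which promotes entry into the cycle, 2.46-fold (1.30 ± 0.18), with limma adjusted p between 0.00507 and 0.00625. Cdkn1a was detected on 8 of 12 WT arrays and another of its probes differed by 0.94 log2, so the size of that rise is uncertain. The list shift was 0.97 (camera adjusted p = 0.0339, limma), and adjusted p = 0.295 with an estimated correlation. The shift was 0.68 with slide as a fixed block and 0.73 within slide 2, and it did not pass without ZT4 (camera adjusted p = 0.0920, limma) or ZT16 (0.0585). Gadd45g and Ccnd1 were called with each time left out, whereas Cdkn1a had limma adjusted p of 0.0507 without ZT8 and 0.0538 without ZT16. Their differences with the fixed block and within slide 2 were 0.50 and 0.68 for Gadd45g, 1.16 and 1.28 for Ccnd1, and 1.21 and 1.10 for Cdkn1a. Of 9 heat shock genes, 2 fell by both counts, the small chaperone gene Hspb1 (3.43-fold, -1.78 ± 0.13, limma adjusted p = 0.000514, called with each time left out) and the mitochondrial chaperonin gene Hspe1 (1.28-fold, -0.36 ± 0.09, limma adjusted p of 0.0756 to 0.185 with any 1 time left out). The same values were -1.32 and -1.25 for Hspb1 and -0.54 and -0.57 for Hspe1. That list shift was -0.35 (camera adjusted p = 0.0492, limma), and adjusted p = 0.4998 with an estimated correlation. It was 0.15 with slide as a fixed block and -0.13 within slide 2, and it passed without ZT0 or ZT12 but not without ZT4, ZT8, ZT16 or ZT20 (camera adjusted p of 0.111, 0.0585, 0.181 and 0.0501, limma). It did not pass either without WT ZT4 alone (0.0821), without DKO ZT0 alone (0.0795), with median scaling (0.275), among probes detected on all 24 arrays (0.104), or with several single arrays left out. None of the 5 lists that passed did so with slide as a fixed block, where 9 other lists passed.

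Among the other lists, 0 of 13 unfolded protein and amino acid stress genes and 0 of 2 cold-inducible genes passed limma's test over all genes (1 and 1 at an unadjusted p under 0.05), and 1 of the latter, Rbm3 (0.41 ± 0.12 log2, SE, n = 6 times per genotype, limma adjusted p = 0.0665), passed adjusted over the list alone. Of 14 acute phase genes, 1 fell over all genes, Saa4 (2.24-fold, -1.16 ± 0.19), with 1 up and 1 down adjusted over the list alone. Of 6 male-biased genes, Cyp4a12a fell 2.93-fold (-1.55 ± 0.39), and of 3 female-biased genes Cyp17a1 rose, both by either count. Without ZT12 Saa4 had a limma adjusted p of 0.0717, and without ZT0 Cyp4a12a had 0.151. Over the 6 times left out in turn, Saa4 kept the call for 4 and Cyp4a12a for 2. The differences with the fixed block and within slide 2 were -2.22 and -1.19 for Saa4 and -0.09 and -0.91 for Cyp4a12a. The shifts of the 4 lists large enough to test were 0.06, 0.03, -0.08 and 0.70, and none passed (camera adjusted p of 0.549, 0.981, 0.598 and 0.626, limma). The median of the acute phase list was -0.01 while its mean and test pointed up. With slide as a fixed block they were -0.23, -1.33, -1.20 and 5.91, and within slide 2 they were -0.37, -0.14, -0.87 and 3.59.

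Few markers of cell types changed in daily mean. Of 8 hepatocyte markers, 1 fell, Alb, which encodes albumin (1.94-fold, -0.96 ± 0.18 log2, SE, n = 6 times per genotype). Its probe was dim, detected on 8 WT and 1 DKO arrays of 12, although albumin mRNA is abundant in liver, so its value is uncertain. Of 8 macrophage and Kupffer cell markers, 7 were higher in DKO and 0 passed limma's test by either count (3 at an unadjusted p under 0.05), with C1qb at 0.54 ± 0.24. Of 8 endothelial markers Lyve1 rose 1.81-fold (0.86 ± 0.23) by both counts, and the cholangiocyte marker Sox9, the sole measured gene of its list, rose 1.99-fold (0.99 ± 0.21). Sox9 was detected on 6 of 12 WT arrays, so its fold rests partly on undetected signals. None of 6 stellate cell and fibroblast, 2 lymphocyte, 2 erythroid or 3 pancreatic acinar markers passed limma's test over all genes (2, 0, 1 and 2 at an unadjusted p under 0.05), with Acta2 at 0.46 ± 0.21, Ccl5 at 0.37 ± 0.29, Hba-a1 at -0.39 ± 0.23 and Cela2a at 0.57 ± 0.34, and 1 erythroid marker was lower adjusted over the list alone. The highest limma adjusted p with 1 time left out was 0.0764 for Alb (without ZT20), 0.202 for Lyve1 and 0.109 for Sox9 (without ZT12). Over the 6 times left out in turn, Alb kept the call for 4, and Lyve1 and Sox9 kept it for 1. The direction of Alb turned with slide as a fixed block (0.13, and -0.45 within slide 2), while the same values were 1.25 and 1.48 for Lyve1 and 0.20 and 0.56 for Sox9. Another Acta2 probe went the other way (-0.22). The 5 adipocyte markers were not measured. No marker list shift passed (camera adjusted p of 0.389 for hepatocyte, 0.202 for macrophage, 0.681 for endothelial, 0.389 for stellate and 0.766 for acinar markers, limma), but the macrophage list passed with median scaling (shift 0.30, camera adjusted p = 0.0147, limma). In the same order the shifts were -0.16, 0.30, 0.11, 0.16 and 0.20, with slide as a fixed block 0.04, -1.15, -0.15, -0.03 and -0.60, and within slide 2 -0.06, 0.00, 0.09, 0.02 and -0.40.

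**Figure D2:**
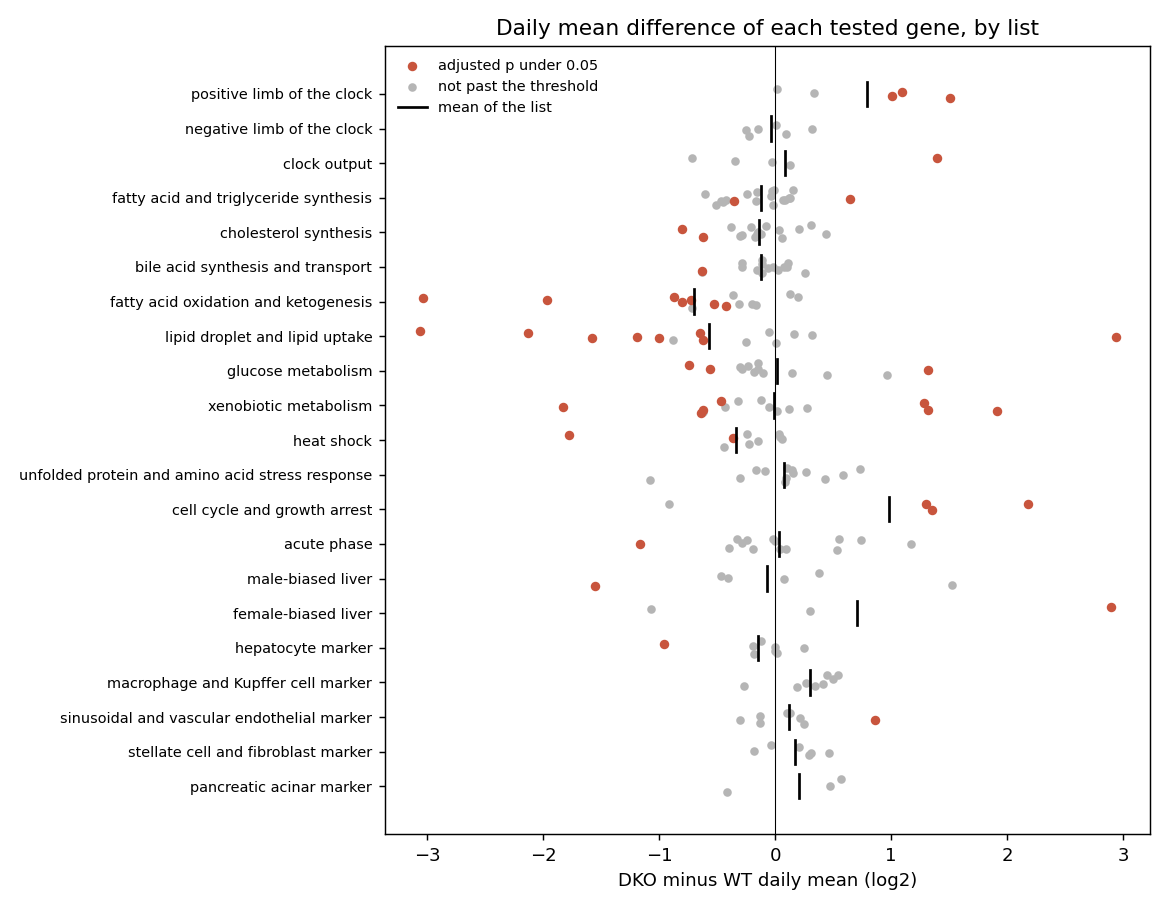
DKO minus WT daily mean (horizontal axis, log2) of each tested gene of the 21 lists with at least 3 measured genes (vertical axis, 1 line per list). Red points passed a limma adjusted p of 0.05 over all genes, grey points did not, and the black bar is the mean of the list; fatty acid oxidation and lipid droplet genes lie mostly left of 0, with Lpl at 2.94 on the right.

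The last comparison was of the genotypes at each time, where 1 RNA sample per genotype gives no spread of its own and no test was run. Genes were counted where the arrays of the genotypes lay at least 2-fold apart. At ZT0, Tff3 (12.25) and the neutrophil and myeloid protease gene Prtn3 (12.34) were bright in DKO and not detected in WT, while Acot1 differed by -3.94 and Gsta2 by -3.69 (DKO minus WT, log2). In that DKO sample 8 of 8 macrophage and Kupffer cell markers lay above the mean of the other DKO times, by a median of 1.16 log2. At ZT4, the endothelial gene Esm1 was higher by 3.43 and Cish, a feedback inhibitor of cytokine and growth hormone signalling, by 2.51 log2, Clstn3 differed by -2.88, and Fitm1 was at 8.88 in WT and not detected in DKO, as it was again at ZT12 (9.36 in WT). Moxd1 was not detected in WT at any of ZT8, ZT12 and ZT16 and stood at 13.27, 12.59 and 12.05 in DKO, but it was at 11.90 in WT at ZT4. Obp2a was higher by 4.31 at ZT8 and 5.03 at ZT16, Cyp4a14 differed by -3.99 and Gsta1 by -3.83 at ZT8, and Wfdc12 was at 9.29 at ZT12 and 10.53 at ZT20 in DKO and not detected in WT. Acot3 was not detected in DKO at ZT12 and was at 11.76 in WT, and at ZT16 it differed by -4.58. At ZT16 the asparagine synthetase gene Asns was at 9.31 in WT and not detected in DKO. At ZT20 the steroid dehydrogenase gene Hsd3b5 was at 12.92 in DKO and 6.99 in WT, against 12.15 to 14.47 at the other WT times, and Cidea and Cidec, bright in WT, were not detected in DKO.

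At least 2-fold differences were counted for 729 genes at 1 or more times. There were 243 up and 107 down at ZT0, 37 and 41 at ZT4, 129 and 108 at ZT8, 106 and 140 at ZT12, 82 and 64 at ZT16, and 105 and 95 at ZT20. At all 6 times Cyp17a1, Cyp2d12, Gm14685, Loxl4, Ntrk2, Tff2 and Wfdc15b were higher and Aatk, Acot1, Clstn3, Dio1, Fitm1, Serpinb1a and Sp5 lower by this count. The total was 310 with the authors' values or with no background correction, 419 with the offset of 50, and 422 among probes detected on all 24 arrays.

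**Figure D3:**
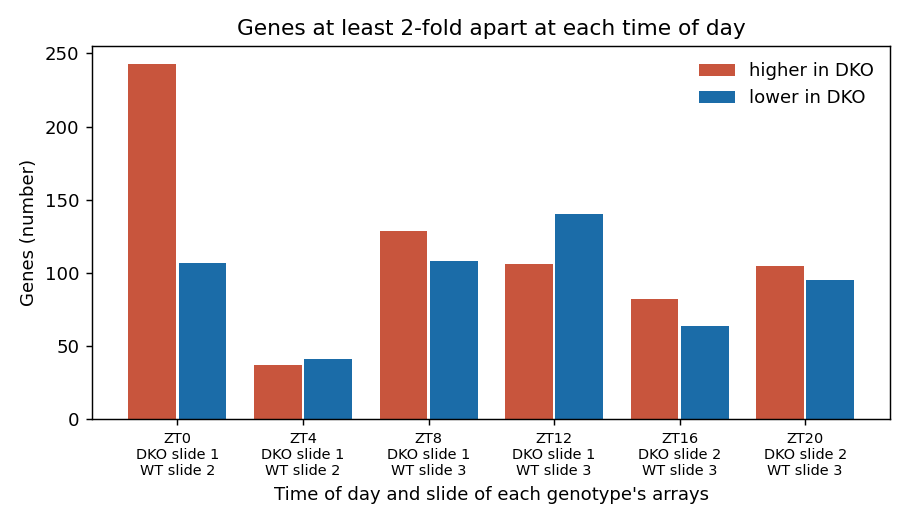
Number of genes (vertical axis) at least 2-fold higher or lower in DKO at each time of day (horizontal axis, with the slide that held each genotype's arrays). ZT0 has 243 higher and 107 lower genes and ZT4 has 37 and 41.

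The slides gave a further view of these differences, added after the data were seen. At ZT8 and ZT12, where DKO lay on slide 1 and WT on slide 3, 93 genes were at least 2-fold higher and 89 at least 2-fold lower in DKO in group means. Each sample was placed for each of these genes on a scale from WT (0) to DKO (1) at those times. On slide 2, DKO ZT16 and ZT20 had median places of 0.942 and 0.98 for the higher genes and 0.698 and 0.676 for the lower genes. WT ZT0 and ZT4 on the same slide had 0.594 and 0.842 for the higher genes and 0.306 and 0.516 for the lower genes, whereas WT ZT16 and ZT20 on slide 3 had 0.112 and 0.297, and 0.0231 and -0.01. DKO lay nearer to the DKO end than WT on slide 2 for 64 of 93 higher genes (68.8%) and 61 of 89 lower genes (68.5%). The median gap on that slide was 0.15 and 0.209 of the difference at ZT8 and ZT12, with interquartile ranges of -0.0638 to 0.512 and -0.0744 to 0.55.

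**Figure D4:**
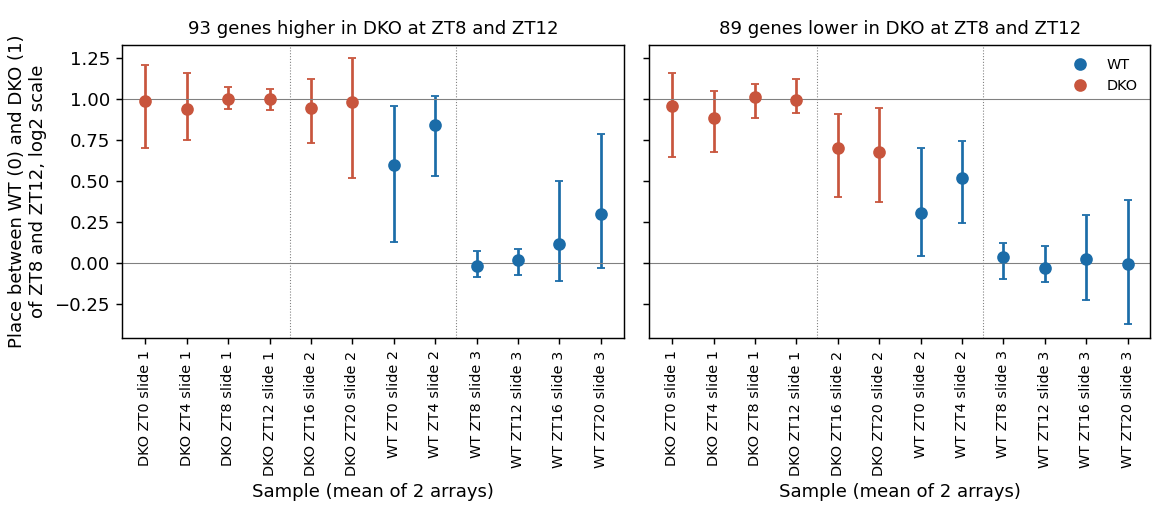
Place of each sample (horizontal axis, grouped by slide) between WT at 0 and DKO at 1 (vertical axis, log2 scale, from ZT8 and ZT12), for the 93 higher and 89 lower genes; points are medians over genes and bars the interquartile range. WT ZT0 and ZT4 on slide 2 lie between the genotypes, at 0.594 and 0.842 for the higher genes.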

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

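The test of rhythm differences over other splits of the samples and the tests of the slides were chosen only after the result was seen. The difference in rhythm between the genotypes passed limma's test adjusted over the 18 clock-list genes alone for Nr1d2 (adjusted p = 0.0008368), Dbp (0.009774), Bhlhe40 (0.04131), Arntl (0.04348), Nampt (0.04348) and Cry2 (0.04672), and for 0 of these over all genes (450 of 7272 genes at an unadjusted p under 0.05). Fitted with slide as a fixed block, Nr1d2 passed adjusted over the list alone (limma adjusted p = 0.03148) and the others did not (0.3081 to 0.5852), and with slide as a random block Nr1d2 (0.0009278) and Dbp (0.01248) passed. Nr1d2 is itself a targeted gene, so with the fixed block no rhythm difference passed in a clock-list gene that was not targeted. At single times, 27 genes were at least 2-fold higher in DKO at 1 time and at least 2-fold lower at another, among them Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, Fgf21, Elovl3, Asns, Mt1, Mt2, Lcn2 and Saa1. That difference between times was not tested. Of 586 detected probes with no gene listed, 71 differed in daily mean (23 up, 48 down), data that the comparisons of genes left out.

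Other groupings of the same samples bear on chance. For the daily mean, 1 of 100 splits of the 12 averages into 6 and 6 gave as many genes, the real one with 677, and the highest other split gave 4. Among the 32 swaps of the genotypes within times 1 gave as many, and the highest other gave 13, so chance is excluded for that count, although slide and genotype go together in the real split. For gene lists, 45 of 100 splits gave at least the 5 lists of the real split, and the highest other gave 12, so chance was not excluded. For the difference in rhythm, 100 of 100 splits and 32 of 32 swaps gave at least the real count of 0 (limma, 450 genes at an unadjusted p under 0.05), with 3 and 182 as the highest others. Every grouping gives at least 0, so this decides nothing about chance. The swap with 182 put DKO ZT0, ZT4 and ZT20 with WT ZT8, ZT12 and ZT16, which turns the difference in daily mean into a step over the day and points to a structure of the samples. Among 60 orders of the times, 1 gave as many rhythmic genes in WT (13, highest other 7) and 1 in DKO (4, highest other 3), so a chance order was excluded for WT. In DKO the margin was 1 gene and leaving out single arrays moved the count from 0 to 5, so little rests on it. This does not exclude the slides, because consecutive times of a genotype shared a slide and a step between slides can resemble a 24 h wave in the real order. Fitted with slide as a fixed block, limma called 0 genes in WT (708 at an unadjusted p under 0.05) and 1 in DKO, which was not among the 4.

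Genes 2-fold apart at ZT8 and ZT12 were measured there with DKO on slide 1 and WT on slide 3. The WT samples of slide 2 lay nearer to DKO than WT ZT16 and ZT20 did, by medians over genes of 0.0443 to 0.541 of the difference. The lower quartile of that excess reached -0.178 (WT ZT0 against WT ZT20, higher genes), so a genotype difference of the same size at every time without a slide effect was not excluded. For an effect of slide alone, the smaller of the median gaps between the genotypes on slide 2 was 0.15 of the difference, which lies between the bounds set for the test, and the interquartile ranges reached below 0. Slide alone and genotype therefore cannot be told apart for these genes as a set, because slide 2 held the genotypes at different times. A genotype difference that varies with the time of day may also give these places and was not tested.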

How the results depend on the processing

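Leaving out the WT ZT4 or DKO ZT0 sample alone, time as a factor together with slide, and the amplitude test with its slide blocks were chosen after the data were seen. The cause was not tested for the changes below, except where fewer genes, samples or calls follow from the setting itself. The counts of 677 genes in daily mean, 13 rhythmic in WT, 4 in DKO, 0 with a difference in rhythm, 5 lists and 729 genes at single times are limma's or counts of size. Of the 54 named genes called in daily mean, 54 were called with the offset of 50, no background correction or the authors' values, 51 with median scaling, 45 with no filter, 47 with an intensity trend and 22 with slide as a random block. With slide as a fixed block 0 of the 54 were called. Without ZT0, ZT4, ZT8, ZT12, ZT16 or ZT20, 36, 43, 24, 25, 21 and 25 were called. The call held whichever of the 6 times was left out for 17 of the 54. Signal over background limits what can be tested, since 34.8 to 40.2% of probes were detected per array.

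The WT rhythm count was 37 with an offset of 50, 43 with no background correction, 123 with median scaling, 49 with the authors' values, 30 among probes detected on all 24 arrays, 26 over all kept probes and 56 with an intensity trend. The DKO rhythm count was 1 with the offset of 50, no background correction or the authors' values, 0 among probes detected on all arrays (405 at an unadjusted p under 0.05) and 7 over all kept probes. The daily mean count was 2182 with median scaling, 1019 over all kept probes and 372 with a 1.5-fold minimum. The count at single times was 419 with the offset of 50, 310 with no background correction, 310 with the authors' values and 422 among probes detected on all arrays, where 1 list passed. With an estimated correlation 0 lists passed (camera in limma, 3 at an unadjusted p under 0.05). Each genotype fitted alone gave 0 rhythmic genes in WT and 0 in DKO (914 and 489 at an unadjusted p under 0.05).

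Arrays of a group share a number with those of other groups, and same-numbered arrays deviated with correlations of -0.053 to 0.054, so the numbers do not pair. With the arrays as separate samples and no block, limma called 2680 genes in daily mean, 1655 and 584 rhythmic in WT and DKO, and 447 with a difference in rhythm. With the replicate number as a block these were 2610, 1521, 516 and 391, and with the group as a random block 1288, 397, 79 and 44. The heat shock list lost its call with the replicate block (adjusted p = 0.0507, camera in limma). The first 2 of these fits take technical arrays as samples.

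With slide as a fixed block, 0 genes were called in daily mean and 0 in WT rhythm (793 and 708 at an unadjusted p under 0.05), 1 in DKO rhythm, 1 in the difference in rhythm, and 9 lists. With time as a factor as well, 0 were called in daily mean (657 at an unadjusted p under 0.05). Directions turned for Nfil3 (-0.058), Acot3 (0.17), Slc2a2 (0.33), Gsta2 (1.66), Alb (0.13), Nr1i2 (0.07) and Aldh1a1 (0.23), none of which passed there. The shifts turned for the negative limb (1.10), fatty acid and triglyceride synthesis (0.82), xenobiotic (0.95), acute phase (-1.33) and macrophage lists (-1.15), which passed there. The clock output list passed there too, with a shift of 1.11 in place of 0.08, and its camera test pointed up in place of down. The mean shift also changed sign for heat shock (0.15), which passed without the block, and for lists that passed under neither setting, namely bile acid (0.16), unfolded protein (-0.23), cold-inducible (-0.39, not tested), hepatocyte (0.04), endothelial (-0.15), stellate (-0.03) and acinar (-0.60). With slide as a random block the counts were 123 in daily mean and 8 in WT rhythm.

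Without ZT0 the counts were 366 in daily mean, 6 in WT rhythm, 0 in DKO rhythm and 1 in the difference in rhythm. Without ZT4 the DKO rhythm count was 2, and 3 lists passed. Daily mean, WT rhythm and DKO rhythm counts were 142, 1 and 0 without ZT8, 149, 2 and 0 without ZT12, 170, 4 and 0 without ZT16, and 197, 4 and 0 without ZT20, with 3 lists without ZT16 and 3 without ZT20. DKO rhythm was 0 without WT ZT4 alone and 0 without DKO ZT0 alone. Where DKO rhythm was 0 with times or samples left out, 349 to 668 genes had an unadjusted p under 0.05. Leaving out single arrays or all arrays of 1 number gave 472 to 721 genes in daily mean, 9 to 22 in WT rhythm, 0 to 5 in DKO rhythm, 0 in the difference in rhythm (limma) and 4 to 5 lists.

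Among other values under the alternatives, 3478 daily means of named genes stayed on their side of the threshold, 335 lost a call, 56 gained one, and 5 that had passed turned direction. The 3478 include genes called under neither setting and the many settings that leave out a single array, so their number is no measure of stability. The mean amplitude difference of the clock-list genes was -0.83 to -0.22 over 40 alternatives, with the slide blocks giving -0.22 (fixed) and -0.64 (random). At single times, 84 values of named genes moved beyond the spread of the arrays and 45 did not.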

Other observations

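All tests of the WT ZT4 and DKO ZT0 samples were chosen only after the result was seen. In the DKO ZT0 sample, genes of immune cells and of the acute phase stood above the other DKO times. The macrophage and Kupffer cell markers were higher by a median of 1.16 log2 (8 of 8), the acute phase genes by 0.71 (13 of 14), the endothelial markers by 0.5 (7 of 8) and the erythroid markers by 0.963 (2 of 2). The erythroid value is the middle of 2 genes, with quartiles of 0.549 and 1.38. Of these, Hba-a1 was at 16.11 with an SD of 0 between arrays, near the highest array signals, so the size of its difference is uncertain. Stellate cell and fibroblast markers differed by -0.0731 and hepatocyte markers by -0.00938, while the fatty acid and triglyceride synthesis list differed by -0.467 and the negative limb of the clock by -0.742. Among genes picked for their level there, the neutrophil gene S100a8 was at 12.16, the acute phase gene Lcn2 at 14.39, the chemokine gene Cxcl13 at 11.83 and the cytokine gene Il1b at 10.35. Lcn2 was also at 12.65 in DKO at ZT8 and at 12.05 in WT at ZT12. With 1 RNA sample there, these are values of that sample.

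In the WT ZT4 sample, Moxd1 was at 11.90, against 5.50 to 5.83 at the other WT times, where it was not detected. On a scale from WT (0) to DKO (1), set by 88 genes higher and 93 lower in DKO at the times from ZT8 to ZT20, WT ZT4 had median places of 0.75 and 0.606. WT ZT0 had 0.418 and 0.301, and the other WT samples, which set the scale, had -0.0338 to 0.0196 and -0.151 to 0.101.

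Slide 2 as the whole cause cannot be told apart from a cause in that sample. WT ZT0 on the same slide lay lower by at least 0.305, but the interquartile range of that gap over genes reached below 0 (-0.0168 and -0.0758), and the WT samples of slide 3, each placed with its own time left out of the choice of genes and of the scale, ranged over 0.424 for the lower genes. A swap with the DKO ZT4 sample was excluded, since that sample lay at 1.02 or above, among the other DKO samples. RNA of DKO liver mixed into the sample may explain the place and cannot be told apart from other causes. The share it needs was a median of 0.647 for the higher and 0.71 for the lower genes. The interquartile ranges over genes, 0.32 to 1.04 and 0.525 to 0.895, overlap by 0.37. They are too wide to show that 1 share holds for all genes, as a mix would need. A difference of the WT liver at that time of day stays open, untested, and without that sample limma called 619 genes in daily mean.

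For the immune genes of DKO ZT0, other explanations were weighed. A rise shared by the other DKO samples of slide 1 was not seen. The genes 2-fold higher at DKO ZT0 differed by a median of 0.0491 log2 between those samples and the DKO samples of slide 2. The 2 sets of samples also differ in time of day, so slide 1 was not excluded. A lower share of hepatocytes with a like rise of every other cell type was not seen. The lower quartile of the macrophage markers lay 0.665 above the upper quartile of the stellate cell and fibroblast markers. Endothelial (0.5) and erythroid markers (0.963) were higher too, so a lower share with unequal rises of other cells was not excluded. The rise in that sample also covered 8 acute phase genes that hepatocytes make, by a median of 0.433 (7 of 8), at percentile 100 of 10000 random lists of matched level. These genes belong to the acute phase list already seen to be high there, so this test cannot decide about immune cells alone. An inflamed liver in the animal or animals of that sample, or an effect of the genotype at that time, may also account for the immune genes, which 1 sample cannot decide. Without that sample limma called 499 genes in daily mean.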
